A study of Homo sapiens with 8 samples.

How the data were processed

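The series holds 8 arrays, 2 for each combination of cell line (HCT116 or CAL27) and treatment (DMSO, or 56 µM spironolactone for 3 days). The sample labels give this time for the treated arrays only and none for the vehicle arrays. Per the labels' protocols, cells were seeded in plates with DMSO or drug and collected by trypsinization, RNA was extracted with TRIzol, and biotinylated cRNA was prepared by the standard Affymetrix protocol. Per the submitters' processing notes, the authors used RMA and Partek 6.3, with no more said of the settings. The deposited table gives 1 value per probe set and array, and its values were read as log2 expression, a scale that no source states and that was inferred from their range of 1.39 to 13.93. Background correction and normalization before deposit are therefore those of the authors, and the scanner files were not analysed here.

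The table held 54715 probe sets, of which 102 array controls were kept out of every test. The platform annotation gave 40920 probe sets exactly 1 gene symbol and 864 several symbols, and did not list 12931, which are unnamed here rather than without a gene. Probe sets with several symbols or none were not used. Symbols were updated through the gene identifier against RefSeq annotation of GRCh38.p14, used for names only, which matched 40864 probe sets, and the other 56 kept the symbol of the annotation. Each of the resulting 19774 genes was represented by the probe set with the highest mean over all 8 arrays. A gene counted as measured when that probe set lay above the table's median (3.21) on at least 2 arrays, which left 13637 genes, and the other 6137 were called dim and left out of the tests. Probe sets of a named gene that went the other way are given with the gene.

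All 8 arrays were fitted in limma 3.58.1 under R 4.3.3 with a mean for each of the 4 groups, which left 4 residual degrees of freedom and assumes that the lines vary alike. Variances were moderated with a mean-variance trend. The contrasts were drug minus vehicle in HCT116, the same in CAL27, their average, their difference (the interaction, CAL27 minus HCT116), and vehicle CAL27 minus vehicle HCT116. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the 13637 genes. All adjusted p values are from limma. Counts adjusted over the list alone used the same p values, adjusted over a list's measured members. Values in parentheses after ± are the SD of the 2 arrays.

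Before the data were examined, 45 gene lists, the rule for named genes, the tests and all alternatives but 1 were fixed. The lists covered ligands of immune receptors, nuclear receptors and their targets, DNA damage and repair, lipid synthesis, stress responses, cell division and death, invasion, signalling pathways, metabolism, histones, and markers of epithelia, fibroblasts, leukocytes, and erythroid and endothelial cells. The 44 lists with at least 3 measured members were tested with limma's camera at a preset correlation between genes of 0.01 and adjusted over the lists, and again with an estimated correlation and with fry. Named genes were, per line, the 10 risen and 10 fallen genes with the largest log2 difference among those that passed and whose treated arrays both lay beyond both vehicle arrays. For each list they were the 2 to 4 members with the largest difference among those that passed, or up to 2 where none passed. For the interaction they were the 5 in each direction, and for the vehicle comparison 4 members each of the intestinal and squamous lists. NKG2D ligands found among the 19774 genes, RXRA, RXRB, RXRG, ATM, CHEK2, NR3C2 and ERCC3 were always given.

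The numbers in the sample titles fall in 2 runs that each hold 1 array of every group, and this pairing was checked through the deviations of arrays from their group means. Same-run arrays deviated together in all 6 pairs of groups, with correlations across genes of 0.112 to 0.348, and the poly-A control transcripts also parted the runs. The run may thus be a batch, but the main fit did not include it, so its p-values ignore this pairing. A fit with the run as a block is given where it changed a list call or moved a gene count by over 1.5 times. Single genes that passed only with the block are not named. Statements that a gene did not pass hold for the fit without it. Because each run holds every group once, the block leaves the log2 differences unchanged. Within 1 run a group has 1 array, so runs give values but no test.

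Alternatives changed 1 choice at a time: the mean of all probe sets of a gene; leaving out probe sets whose suffix marks probes that may bind several transcripts; no filter, or a filter at the 75th percentile; cyclic loess or median centring; no variance trend, or no moderation; the arrays of 1 line alone; the run as a block; a 2-fold threshold; camera with an estimated correlation and fry; and leaving out each array in turn. The scripts were tested on simulated data with 13637 genes, of which 100 were changed by 1 and 100 by 2 on the log2 scale. For HCT116 the fit recovered 31% and 80% of these, for CAL27 23% and 80%, for the average 62% and 92%, and for the interaction 7% and 52%. It made 3, 6, 9 and 3 false calls in these comparisons, and a shifted list was recovered while 0 unshifted lists were called. The simulated genes varied independently of each other and without a run effect. The simulation therefore cannot show how often camera calls lists falsely when their genes vary together, as at an estimated correlation of 0.951 for G2 and mitosis.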

Results

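Transcript levels were measured on 8 Affymetrix arrays of total RNA from HCT116, a human colorectal carcinoma line, and CAL27, a human squamous carcinoma line of the tongue. Each line was grown with the vehicle DMSO, or for 3 days with 56 µM spironolactone, a steroidal antagonist of the mineralocorticoid receptor. The sample labels state no time for the vehicle arrays. The 4 groups held 2 arrays each. The title of the series names NKG2D ligands, metastasis and RXR-gamma, and the contrasts of drug with vehicle address whether transcripts of these families changed.

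Values spanned 1.39 to 13.93 on the log2 scale, array medians lay between 3.20 and 3.24, and 13637 of 19774 genes were bright enough to be tested. Across genes, which are not independent replicates, the arrays of a group correlated at 0.975 in vehicle HCT116, 0.989 in treated HCT116, 0.980 in vehicle CAL27 and 0.990 in treated CAL27. The first principal component, 78.1% of the variance, parted the lines, and the next, 10.4%, parted drug from vehicle. Sample titles fell in 2 runs of numbers, each with 1 array of every group, and the poly-A control transcripts lay at 5.17 to 5.67 in run 1 and at 6.04 to 6.35 in run 2. The hybridisation control BioB lay at 9.50 in vehicle HCT116 array 1 and at 7.18 to 8.24 in the other 7 arrays. The number of arrays limits the precision. The labels do not say that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

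Transcripts of 2 NKG2D ligands, the stress-induced surface proteins that the activating receptor NKG2D of natural killer cells binds, rose with spironolactone in both lines. MICB went from 8.11 ± 0.24 (SD, n = 2) to 9.26 ± 0.007 in HCT116, a 2.21-fold rise (log2 1.14, SE 0.21, adjusted p = 0.0181), and from 7.87 ± 0.41 to 8.78 ± 0.025 in CAL27, a 1.88-fold rise (log2 0.91, SE 0.21, adjusted p = 0.0343). ULBP2 went from 7.35 ± 0.61 to 8.44 ± 0.19 in HCT116, a 2.14-fold rise (log2 1.10, SE 0.29, adjusted p = 0.0471), and from 8.20 ± 0.37 to 9.62 ± 0.11 in CAL27, a 2.69-fold rise (log2 1.43, SE 0.29, adjusted p = 0.0238). Both treated arrays lay above both vehicle arrays for each gene in each line. Within the runs MICB differed by 1.32 and 0.97 in HCT116 and by 1.22 and 0.60 in CAL27, and ULBP2 by 1.40 and 0.80 in HCT116 and by 1.61 and 1.25 in CAL27. The rises did not differ detectably between the lines: CAL27 minus HCT116 was -0.23 for MICB (adjusted p = 0.808) and 0.33 for ULBP2 (adjusted p = 0.80). On average over both lines MICB rose by 1.03 (adjusted p = 0.00398) and ULBP2 by 1.26 (adjusted p = 0.00559). RAET1E did not pass, at 0.40 (adjusted p = 0.496) in HCT116 and 0.50 (adjusted p = 0.408) in CAL27, while ULBP1 and ULBP3 were dim in every group. The values of RAET1E, 3.23 to 4.19, lay close to the table's median of 3.21. MICA, RAET1G and RAET1L, also on the fixed list, were not among the 19774 genes, so nothing can be said of them. Whether the probe sets of MICB and ULBP2 also bind transcripts of these genes was not checked.

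As a list, 2 of the 3 measured NKG2D ligands rose in each line, the same number as when adjusted over the list alone. Its median was 0.91 in CAL27 (camera adjusted p = 0.0204), a call that was lost at adjusted p = 0.342 with an estimated correlation. In HCT116 the median was 1.10 (camera adjusted p = 0.0666), and the list passed with the run as a block (adjusted p = 0.0444) but not at adjusted p = 0.882 with an estimated correlation. The calls were lost without vehicle array 1, treated array 1 or treated array 2 of the line. In HCT116 MICB then differed by 0.97 to 1.15 (adjusted p = 0.067 to 0.166) and ULBP2 by 0.66 to 1.23 (adjusted p = 0.153 to 0.21). In CAL27 MICB differed by 0.62 to 0.93 (adjusted p = 0.116 to 0.22) and ULBP2 by 1.17 to 1.51 (adjusted p = 0.0918 to 0.166). Without treated array 1 or 2 of the other line, ULBP2 in HCT116 (0.0885 and 0.0882) and MICB in CAL27 (0.0697 and 0.0688) also lost their calls with unchanged differences. ULBP2 in HCT116 did not pass either, at 1.01 to 1.10, with the mean of its probe sets (adjusted p = 0.0573), without the filter on low values (0.0543), after cyclic loess (0.0619), without the variance trend (0.0743) or with the 4 HCT116 arrays alone (0.0885). MICB in CAL27 did not pass without the trend (adjusted p = 0.0611) or with the 4 CAL27 arrays alone (0.0643), and neither gene passed in either line without moderation (0.105 to 0.194).

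**Figure D1:**
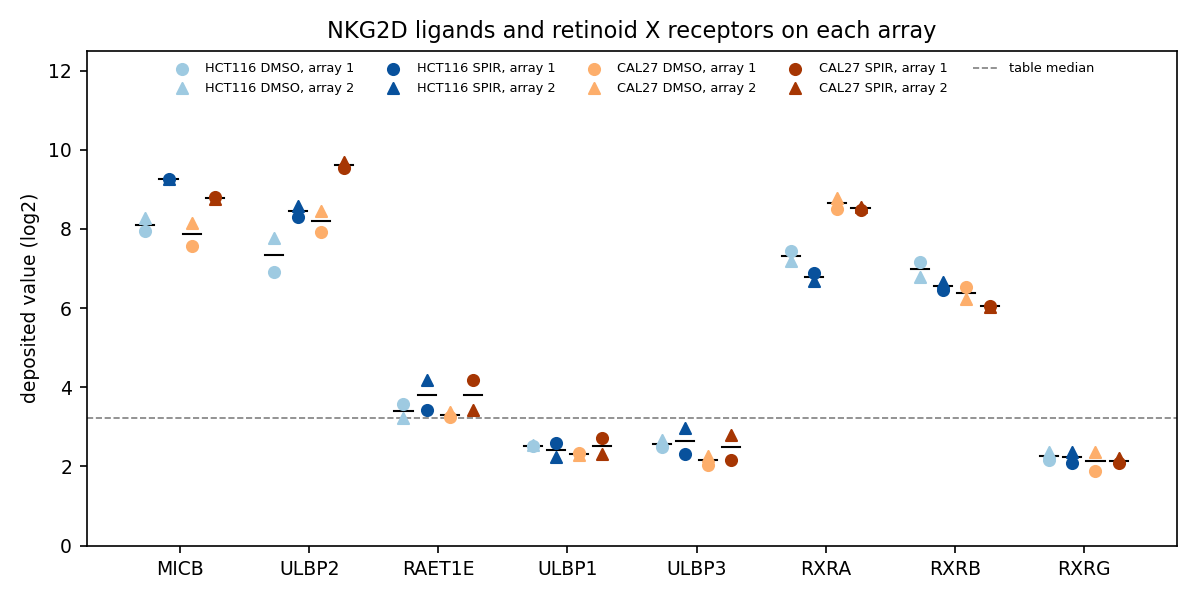
Deposited log2 values of NKG2D ligands and RXR genes on each of the 8 arrays, with circles for array 1, triangles for array 2, a black line for the group mean and a dashed line for the median of the table. MICB and ULBP2 lay higher in all treated arrays than in the vehicle arrays of the same line, and RXRG stayed between 1.89 and 2.38.

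RXRG, which encodes the nuclear receptor RXR-gamma, was not measurably expressed: its values of 1.89 to 2.38 lay below the table's median of 3.21 on all 8 arrays, with group means of 2.26 and 2.23 in vehicle and treated HCT116 and of 2.13 and 2.15 in vehicle and treated CAL27. The related receptor gene RXRA differed by -0.52 (SE 0.18, adjusted p = 0.0919) in HCT116 and -0.13 (adjusted p = 0.719) in CAL27, and its other probe set differed by 0.66 and 0.25. RXRB differed by -0.42 (adjusted p = 0.242) and -0.34 (adjusted p = 0.384). Neither RXR gene passed in either line. NR3C2, which encodes the mineralocorticoid receptor, also lay below the median of the table, at 2.31 to 2.90. The checkpoint kinase genes ATM (0.07, adjusted p = 0.937, and -0.15, adjusted p = 0.855) and CHEK2 (0.23, adjusted p = 0.695, and 0.06, adjusted p = 0.94) did not pass in HCT116 or CAL27. ERCC3, which encodes the helicase XPB of the transcription and repair complex TFIIH, rose by 0.68 in HCT116 (adjusted p = 0.047) and stood at 0.25 in CAL27 (adjusted p = 0.427), a difference between lines of -0.43 (adjusted p = 0.529). The ERCC3 call in HCT116 was lost when any of the 8 arrays was left out (adjusted p = 0.0514 to 0.303).

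On metastasis, the fixed lists were those of matrix proteases and invasion and of the epithelial to mesenchymal transition, and neither was called as a list in either line. Of 31 matrix protease and invasion genes 2 fell in HCT116, the integrin subunit ITGB4 by 1.13 (adjusted p = 0.0443) and the hyaluronan receptor CD44 by 0.96 (adjusted p = 0.0185), and 29 did not pass (1 lower when adjusted over the list alone), although 10 other probe sets of CD44 ranged from -0.12 to 1.80. In CAL27 4 rose, 3 fell and 24 did not pass (6 higher and 5 lower when adjusted over the list alone). The collagenase and stromelysin genes MMP10, MMP1 and MMP13 fell by 5.50, 4.14 and 4.11, and the cell adhesion gene L1CAM rose by 2.22 (adjusted p = 0.0152), with another probe set at -0.17. The medians of this list were -0.01 in HCT116 (camera adjusted p = 0.364) and 0.22 in CAL27 (camera adjusted p = 0.578), where the mean had the other sign, at -0.31. Of 23 genes of the epithelial to mesenchymal transition the splicing regulator ESRP1 fell in HCT116, by 1.30 (adjusted p = 0.0219), and 22 did not pass, with a median of 0.09 (camera adjusted p = 0.96). In CAL27 N-cadherin, encoded by CDH2, rose by 1.84 (adjusted p = 0.0162), SPARC by 1.12 and EPCAM by 0.59, and the claudin gene CLDN7 fell by 1.96 (adjusted p = 0.00488), so that 3 rose, 1 fell and 19 did not pass, with a median of 0.22 (camera adjusted p = 0.711). Counts for this list were the same when adjusted over the list alone. The difference between the lines did not pass for CDH2 (1.96, adjusted p = 0.137), L1CAM (2.57, adjusted p = 0.118), MMP10 (-5.47, adjusted p = 0.0967), MMP1 (-4.13, adjusted p = 0.144) or MMP13 (-4.40, adjusted p = 0.167). The 3 MMP genes lay below the table's median in vehicle HCT116, where no fall can be seen.

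In HCT116, spironolactone changed 1379 of 13637 genes, 772 higher and 607 lower. The largest fitted rise was that of NAV3, a microtubule-associated protein of the navigator family, at 16.7-fold (log2 4.06, SE 0.35, adjusted p = 0.00609). THBS1, the matrix glycoprotein thrombospondin, rose by 3.55 on the log2 scale at its brightest probe set (SE 0.60, adjusted p = 0.015). NRP1, a co-receptor of semaphorins and VEGF, rose 7.33-fold (log2 2.87, adjusted p = 0.0156). CD274, which encodes the checkpoint ligand PD-L1, went from 3.24 ± 0.92 to 5.92 ± 0.50 (SD, n = 2), a rise of 2.69 (SE 0.42, adjusted p = 0.0133). The remaining 6 of the 10 genes with the largest rises were the long noncoding RNA MIR31HG (2.72), the hair keratin-associated gene KRTAP2-2 (2.62), the ribosome assembly factor RBM19 (2.60), the secretory chaperone gene SCG5 (2.41), the formin INF2 (2.34) and the spindle protein gene TROAP (2.33). Other probe sets of RBM19 (-0.02), INF2 (-0.10) and TROAP (-0.04) stood near 0, and those of THBS1 ranged from -0.13 to 2.77. Vehicle means of THBS1 (2.79), KRTAP2-2 (2.65) and SCG5 (2.28) lay below the table's median of 3.21. Their rises are thus lower bounds for these probe sets alone, and their places among the largest are not fixed.

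The genes with the largest fitted falls in HCT116 were ERGIC1, of the early secretory pathway, by 2.91 (SE 0.58, adjusted p = 0.0223), the palmitoyltransferase gene ZDHHC11 by 2.89 (adjusted p = 0.024) and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, by 2.78 (adjusted p = 0.0113). The intermediate filament gene SYNM fell by 2.73 (adjusted p = 0.00609) and the vesicle GTPase gene RAB26 by 2.68 (adjusted p = 0.014). C1RL fell by 2.64, CYS1 by 2.63, the pentose phosphate enzyme gene PGLS by 2.61, the deadenylase subunit gene PAN2 by 2.60 and the gasdermin gene GSDMB by 2.53. The other probe set of C1RL stood at -0.62, and those of GSDMB at -1.14 and 0.05. Treated means of SYNM (3.08) and CYS1 (3.01) lay below the table's median, so their falls are lower bounds and the order of the falls is not fixed.

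Genes of the ATF4 and amino acid stress response, which make and import amino acids, shifted downward in HCT116, with 7 of 31 measured members lower, 0 higher and 24 not passing (9 lower when adjusted over the list alone). Besides PCK2, the asparagine synthetase gene ASNS fell by 2.44 (adjusted p = 0.023), the mTORC1 inhibitor DDIT4 by 2.16 (adjusted p = 0.00609) and the serine synthesis gene PHGDH by 1.54 (adjusted p = 0.0217). The median was -0.68, with -0.66 in run 1 and -0.63 in run 2 (camera adjusted p = 4.32e-07, and adjusted p = 0.882 with an estimated correlation). Heat shock proteins, the cytosolic and mitochondrial chaperones, shifted upward, with 7 of 14 higher, 0 lower and 7 not passing (9 higher when adjusted over the list alone). HSPH1 rose by 1.25 (adjusted p = 0.00893), HSPA4 by 1.15 (adjusted p = 0.00994), HSPE1 by 0.88 (adjusted p = 0.023) and DNAJA1 by 0.76 (adjusted p = 0.0129), while another probe set of HSPA4 stood at -0.96. The median of this list was 0.59, with 0.66 and 0.45 within the runs (camera adjusted p = 3.19e-05, and adjusted p = 0.423 with an estimated correlation).

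Cell-division genes stood higher in treated HCT116 as groups, although few passed singly. Of 32 G2 and mitosis genes 0 passed, also when adjusted over the list alone, but 31 were positive, with BUB1 at 1.61 (adjusted p = 0.0817) and ANLN at 1.58 (adjusted p = 0.0633). Their median was 0.89, with 1.36 and 0.44 within the runs (camera adjusted p = 9.63e-06, and adjusted p = 0.922 with an estimated correlation). Of 30 genes of S-phase and DNA replication 3 rose and 27 did not pass, the same number as when adjusted over the list alone. These were the helicase subunit gene MCM4 at 1.37 and the clamp loader genes RFC3 at 0.97 and RFC4 at 0.74. The list's median was 0.68, with 0.93 and 0.38 within the runs (camera adjusted p = 6.93e-05, and adjusted p = 0.922 with an estimated correlation). Ribosome biogenesis genes shifted upward as well, with 7 of 25 higher and 18 not passing (8 higher when adjusted over the list alone), among them PPAN at 1.57, UTP20 at 1.42, POLR1A at 1.15 and TSR1 at 1.03, whose other probe sets ranged from -0.51 to 1.29. Their median was 0.47, with 0.59 and 0.41 within the runs (camera adjusted p = 8.9e-05, and adjusted p = 0.882 with an estimated correlation). Of 21 genes of DNA damage sensing and checkpoint 3 rose and 18 did not pass (6 higher and 1 lower when adjusted over the list alone): RAD50 at 1.02, with another probe set at -0.85, TOPBP1 at 0.81 and MDC1 at 0.80. The median was 0.47, with 0.61 and 0.28 within the runs (camera adjusted p = 0.0255, and adjusted p = 0.882 with an estimated correlation).

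Among 23 genes of MAPK feedback and the immediate early response 4 fell in HCT116, 1 rose and 18 did not pass (7 lower and 1 higher when adjusted over the list alone). FOS fell by 1.59 (adjusted p = 0.0235), DUSP6 by 0.94 and JUN by 0.91, and FOSL1 rose by 0.88. The median was -0.47, with -0.32 and -0.75 within the runs (camera adjusted p = 0.0018, and adjusted p = 0.423 with an estimated correlation). Among 12 targets of the mineralocorticoid and glucocorticoid receptors 4 fell, 1 rose and 7 did not pass (6 lower and 2 higher when adjusted over the list alone). SCNN1A, an epithelial sodium channel subunit, fell by 2.33 (adjusted p = 0.0186) with its other probe sets near 0, KLF9 fell by 1.40 (adjusted p = 0.0374) and TSC22D3 by 1.12 (adjusted p = 0.0157). The kinase gene SGK1, a target that aldosterone induces, rose by 2.09 (adjusted p = 0.012). The median of these targets was -0.48, with -0.47 and -0.53 within the runs (camera adjusted p = 0.0218, and adjusted p = 0.566 with an estimated correlation). For hypoxia and glycolysis 2 of 27 genes fell and 25 did not pass, as when adjusted over the list alone: the mitophagy receptor gene BNIP3L by 1.48 and the collagen hydroxylase gene P4HA1 by 1.06. Their median was -0.41, with -0.11 and -0.74 within the runs (camera adjusted p = 0.0248, and adjusted p = 0.922 with an estimated correlation). The unfolded protein response of the endoplasmic reticulum had 0 of 22 genes passing, also over the list alone, and a median of -0.49 (camera adjusted p = 0.0168, and adjusted p = 0.922 with an estimated correlation), which was -0.96 in run 1 and 0.04 in run 2 and so did not hold within run 2. HERPUD1 stood at -1.34 (adjusted p = 0.134) and EDEM1 at -1.26 (adjusted p = 0.0543).

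The 1379 calls came from limma with Benjamini-Hochberg adjustment over 13637 genes, 3857 of which had an unadjusted p under 0.05. Of the calls 617 were at least 2-fold, and both treated arrays lay beyond both vehicle arrays for every called gene and for 7528 genes in all, 55.2% where chance gives 33.3%. With the run as a block 2255 genes passed, among them all 1379. The share of higher calls was 56.0%, and 43.7% after cyclic loess, so the direction of the majority is not settled. The count was 364 without vehicle array 1, 0 without treated array 1 and 241 without treated array 2 of HCT116, and 518 and 519 without treated array 1 and 2 of CAL27, which share in the estimate of the spread. When probe sets that may bind several transcripts were left out, the number of lists called by camera went from 10 to 3, those of ATF4 and amino acid stress, S-phase and DNA replication, and G2 and mitosis. The other medians were then 0.17 for DNA damage sensing (adjusted p = 0.476), 0.38 for heat shock proteins (0.184), 0.46 for ribosome biogenesis (0.0522), -0.48 for mineralocorticoid and glucocorticoid receptor targets (0.249), -0.37 for MAPK feedback (0.0666), -0.70 for hypoxia (0.0935) and -0.41 for the unfolded protein response (0.0666). With an estimated correlation 0 lists passed (smallest adjusted p = 0.423), and fry, which does not compare a list with other genes, called 1, the heat shock proteins (adjusted p = 0.0236).

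**Figure D2:**
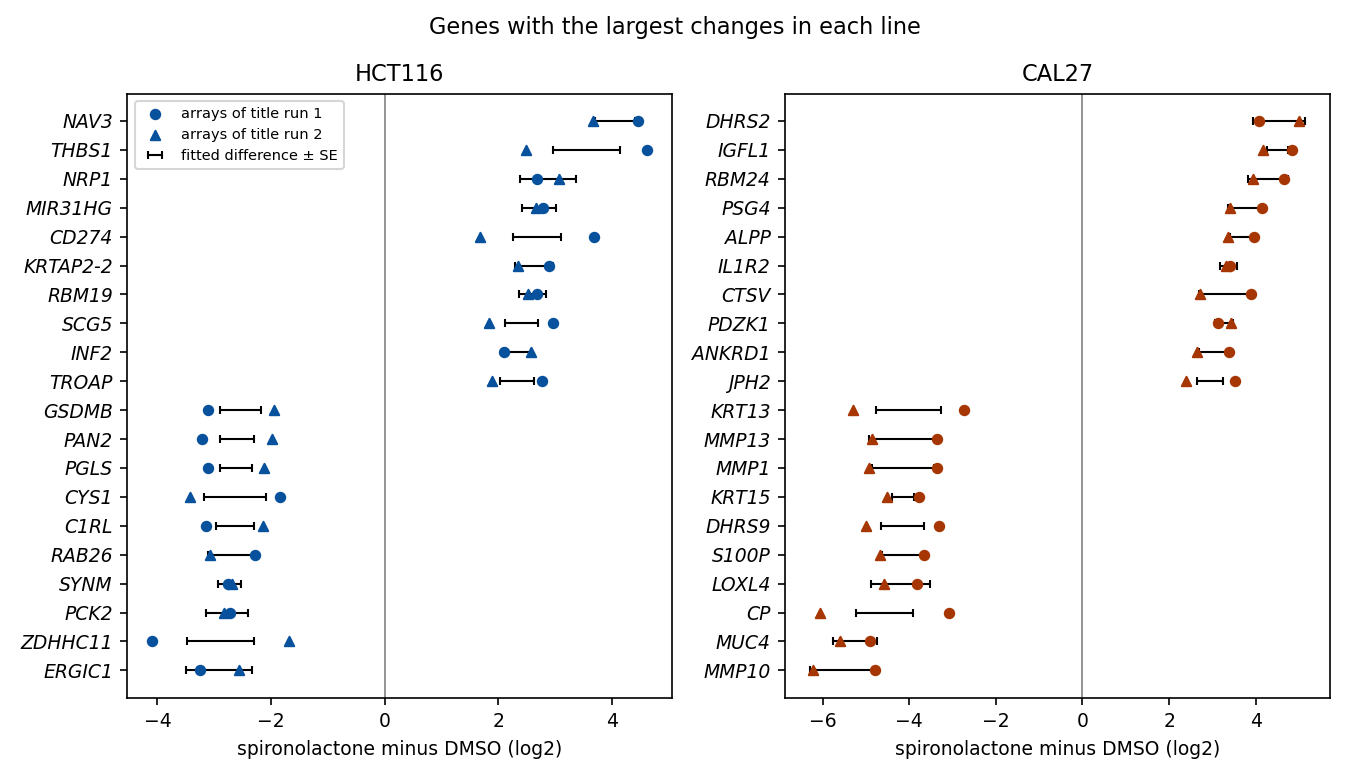
Fitted log2 difference between spironolactone and vehicle (bars, with SE) for the 10 genes with the largest fitted rises and the 10 with the largest fitted falls in each line, with the difference in run 1 as circles and in run 2 as triangles. The fitted differences ran from -2.91 to 4.06 in HCT116 and from -5.50 to 4.54 in CAL27.

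In CAL27, spironolactone changed 1119 of 13637 genes, 615 higher and 504 lower. The largest fitted fall was that of MMP10, a secreted matrix metalloproteinase, from 8.95 ± 1.98 to 3.44 ± 0.97 (SD, n = 2), a decrease of 5.50 on the log2 scale (SE 0.79, adjusted p = 0.00864). The metalloproteinase genes MMP1 and MMP13 fell by 4.14 (adjusted p = 0.0145) and 4.11 (adjusted p = 0.022). The membrane mucin gene MUC4 fell by 5.26 (SE 0.51, adjusted p = 0.00265), with 2 of its 3 other probe sets lower too and the remaining one at 0.03. The copper carrier gene CP, ceruloplasmin, fell by 4.56 (adjusted p = 0.00868), the lysyl oxidase gene LOXL4 by 4.21 (adjusted p = 0.0117) and the calcium-binding protein gene S100P by 4.16 (adjusted p = 0.00404). The retinol dehydrogenase gene DHRS9 fell by 4.16 and the epithelial keratins KRT15 and KRT13 by 4.15 and 4.02. Treated means of CP (2.91) and KRT13 (2.44) lay below the table's median, so their falls are lower bounds and the order of the falls is not fixed.

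The largest fitted rises in CAL27 were those of the reductase gene DHRS2, at 23.2-fold (log2 4.54, SE 0.60, adjusted p = 0.00702), IGFL1, an insulin growth factor-like gene, at 22.8-fold (log2 4.51, SE 0.24, adjusted p = 0.000307) and the RNA-binding protein gene RBM24, by 4.29 (adjusted p = 0.00341). IL1R2, a decoy receptor of interleukin-1, rose by 3.37 (adjusted p = 0.000307), the cathepsin gene CTSV by 3.30 (adjusted p = 0.0186), the scaffold gene PDZK1 by 3.27 (adjusted p = 0.000358), ANKRD1 by 3.02 (adjusted p = 0.00362) and the junctophilin gene JPH2 by 2.95 (adjusted p = 0.00265), with its other probe set at 1.20. Rises of the pregnancy glycoprotein gene PSG4 (3.78) and the placental phosphatase gene ALPP (3.66) are uncertain as to the gene, since near-identical paralogs share their sequence. In 5 of these 10 genes, RBM24, ALPP, IL1R2, PDZK1 and ANKRD1, the vehicle mean lay below the table's median. Their rises are lower bounds, and the order of the rises is not fixed.

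Interferon response genes, which encode antiviral effectors and their regulators, shifted downward in CAL27. Of 35 measured members 14 fell, 0 rose and 21 did not pass (24 lower when adjusted over the list alone), and all 35 were negative. MX2 fell by 2.17 (adjusted p = 0.00544), RSAD2 by 1.79 (adjusted p = 0.00798), IFI44L by 1.76 (adjusted p = 0.00575) and ISG20 by 1.35 (adjusted p = 0.0098). The median was -1.0, with -0.92 and -1.08 within the runs (camera adjusted p = 1.08e-14, and adjusted p = 0.268 with an estimated correlation). NF-kappaB targets, chiefly chemokines and inflammatory mediators, had 9 of 24 lower, 0 higher and 15 not passing (13 lower and 1 higher when adjusted over the list alone). The chemokine genes CCL20 and CXCL2 fell by 2.80 (adjusted p = 0.00238) and 2.04 (adjusted p = 0.0169), LCN2 by 2.43 and TNFAIP2 by 2.38. The median was -0.81, with -0.76 and -0.75 within the runs (camera adjusted p = 1.17e-06, and adjusted p = 0.247 with an estimated correlation), but -0.24 without probe sets that may bind several transcripts (adjusted p = 0.0244). Of 18 genes of HLA class I antigen presentation 1 fell, the immunoproteasome subunit PSMB10 by 1.42 (adjusted p = 0.00702), and 17 did not pass, as when adjusted over the list alone. Their median was -0.37, with -0.34 and -0.30 within the runs (camera adjusted p = 0.00244, and adjusted p = 0.612 with an estimated correlation).

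MAPK feedback and immediate early genes also shifted downward in CAL27, with 12 of 23 lower, 0 higher and 11 not passing (12 lower and 3 higher when adjusted over the list alone). EGR3 fell by 3.64 (adjusted p = 0.04), FOS by 2.29 (adjusted p = 0.0081), FOSB by 2.16 (adjusted p = 0.0196) and DUSP5 by 2.04 (adjusted p = 0.0106). The median was -0.85, with -0.91 and -0.80 within the runs (camera adjusted p = 0.000128, and adjusted p = 0.247 with an estimated correlation). Genes of the cornified envelope and squamous differentiation had 4 of 20 lower, 0 higher and 16 not passing (10 lower and 1 higher when adjusted over the list alone). Besides KRT13, the epithelial transcription factor gene ELF3 fell by 2.40 (adjusted p = 0.00488), SPRR3 by 1.78 (adjusted p = 0.038) and SPRR2B by 1.54 (adjusted p = 0.0381). The median was -0.91, with -0.75 and -0.64 within the runs (camera adjusted p = 0.00068, and adjusted p = 0.352 with an estimated correlation). Apoptosis regulators had 4 of 19 lower and 15 not passing (5 lower when adjusted over the list alone), with the proapoptotic HRK down by 1.41, BIK by 0.89 and PMAIP1 by 0.67, and the antiapoptotic MCL1 by 0.95. Their median was -0.32, with -0.32 and -0.43 within the runs (camera adjusted p = 0.00244, and adjusted p = 0.268 with an estimated correlation).

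Of 11 LXR targets 4 fell in CAL27, 0 rose and 7 did not pass (5 lower and 1 higher when adjusted over the list alone): the lipogenic regulator SREBF1 by 2.32 (adjusted p = 0.00488), the desaturase SCD by 2.24 (adjusted p = 0.000307), the cholesterol exporter ABCA1 by 1.85 (adjusted p = 0.0422) and LPCAT3 by 1.22 (adjusted p = 0.0416), whose other probe set stood at 0.25. The median was -0.86, with -0.89 and -0.83 within the runs (camera adjusted p = 0.00165, and adjusted p = 0.291 with an estimated correlation). Fatty acid synthesis had 4 of 13 lower and 9 not passing (4 lower and 1 higher when adjusted over the list alone). FASN was down by 1.54 and ACSS2 by 0.99, beside SREBF1 and SCD, which are on both lists, so the 2 lists are not separate evidence. Its median was -0.25, with -0.23 and -0.25 within the runs (camera adjusted p = 0.0237, and adjusted p = 0.342 with an estimated correlation), and turned to 0.19 when probe sets that may bind several transcripts were left out. Cholesterol synthesis and uptake had 3 of 21 lower and 18 not passing (7 lower and 1 higher when adjusted over the list alone), with STARD4 down by 1.43, INSIG1 by 1.40 and DHCR7 by 0.71. The median was -0.21, with -0.02 and -0.37 within the runs (camera adjusted p = 0.00918, and adjusted p = 0.484 with an estimated correlation). Of 12 retinoic acid targets 3 fell, 1 rose and 8 did not pass (4 lower and 1 higher when adjusted over the list alone). The retinaldehyde reductase DHRS3 fell by 3.62 (adjusted p = 0.00865), the retinol carrier receptor STRA6 by 1.87 and PLAAT4 by 1.02, and the receptor gene RARA rose by 0.90 (adjusted p = 0.0469). The median was -0.43, with -0.33 and -0.60 within the runs (camera adjusted p = 0.0477, and adjusted p = 0.342 with an estimated correlation), and the call was lost after cyclic loess (-0.42, adjusted p = 0.102). Mineralocorticoid and glucocorticoid receptor targets had 5 of 12 lower, 1 higher and 6 not passing (6 lower and 2 higher when adjusted over the list alone), with SCNN1A down by 2.98, DUSP1 by 1.66 and SGK1 by 1.46. The ubiquitin ligase gene NEDD4L rose by 1.34, with other probe sets from -0.18 to 0.62. The median was -0.58, with -0.54 and -0.59 within the runs (camera adjusted p = 0.0165, and adjusted p = 0.291 with an estimated correlation).

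Lists of cell division shifted upward in CAL27 too. Of 32 G2 and mitosis genes 9 rose, 0 fell and 23 did not pass (28 higher when adjusted over the list alone), among them ANLN by 2.14 (adjusted p = 0.03), HMMR by 1.89 (adjusted p = 0.0288), BIRC5 by 1.87 (adjusted p = 0.0461) and TTK by 1.83 (adjusted p = 0.0314). The median was 1.34, with 1.85 and 0.84 within the runs (camera adjusted p = 4.13e-12, and adjusted p = 0.553 with an estimated correlation). For S-phase and DNA replication 2 of 30 rose and 28 did not pass (7 higher when adjusted over the list alone), MCM10 by 1.64 and RFC3 by 1.31. The median was 0.72, with 0.95 and 0.42 within the runs (camera adjusted p = 3.81e-06, and adjusted p = 0.719 with an estimated correlation). In DNA damage sensing and checkpoint 4 of 21 rose and 17 did not pass (7 higher when adjusted over the list alone): CHEK1 by 1.74, MDC1 by 1.31, BRCA1 by 0.86 and TOPBP1 by 0.85. The median was 0.36, with 0.40 and 0.39 within the runs (camera adjusted p = 0.00163, and adjusted p = 0.342 with an estimated correlation). Core histones had 4 of 9 higher and 5 not passing (6 higher and 1 lower when adjusted over the list alone), H2BC4 by 1.42, H4C8 by 1.35, H2BC12 by 1.23 and H2BC5 by 0.89, and a median of 1.23, with 1.10 and 1.19 within the runs (camera adjusted p = 0.00165, and adjusted p = 0.355 with an estimated correlation).

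Of 14 heat shock proteins 3 rose in CAL27 and 11 did not pass (8 higher and 1 lower when adjusted over the list alone): HSPH1 by 0.87, HSP90AA1 by 0.65 and HSPA4 by 0.64, with another probe set of HSPA4 at -1.09. The median was 0.40, with 0.53 and 0.40 within the runs (camera adjusted p = 0.00165, and adjusted p = 0.291 with an estimated correlation). Ribosome biogenesis had 1 of 25 higher, NOP58 by 0.60, and 0 when adjusted over the list alone. Its median was 0.27, with 0.03 and 0.49 within the runs (camera adjusted p = 0.00723, and adjusted p = 0.768 with an estimated correlation). Of 31 ATF4 and amino acid stress genes 6 fell, 1 rose and 24 did not pass (9 lower and 1 higher when adjusted over the list alone), with DDIT4 down by 2.58 (adjusted p = 0.000892), NUPR1 by 2.14, ATF3 by 1.77 and WARS1 by 1.73. The median was -0.38 (camera adjusted p = 0.00186, and adjusted p = 0.768 with an estimated correlation), but -0.91 in run 1 and 0.24 in run 2, so the shift did not hold within run 2. For the unfolded protein response 0 of 22 genes passed, also over the list alone, with CRELD2 at -1.54 (adjusted p = 0.165) and HYOU1 at -1.30 (adjusted p = 0.224). Its median was -0.69, with -1.22 and -0.11 within the runs (camera adjusted p = 0.00068, and adjusted p = 0.768 with an estimated correlation). For hypoxia and glycolysis 0 of 27 passed, also over the list alone, with ALDOC at -1.37 (adjusted p = 0.276) and EGLN3 at -1.14 (adjusted p = 0.381), and the median was -0.42, with -0.20 and -0.63 within the runs (camera adjusted p = 0.00545, and adjusted p = 0.768 with an estimated correlation).

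The 1119 calls came from the same limma fit, with 3537 genes at an unadjusted p under 0.05. Of the calls 689 were at least 2-fold, and both treated arrays lay beyond both vehicle arrays for every called gene and for 7904 genes in all, 58.0% where chance gives 33.3%. With the run as a block 1904 genes passed, among them all 1119. The share of higher calls was 55.0%, and 45.5% after cyclic loess, so the direction of the majority is not settled. The count was 10 without treated array 1, 180 without treated array 2 and 572 without vehicle array 1 of CAL27, and 594 and 598 without treated array 1 and 2 of HCT116. Camera called 21 lists, 0 passed with an estimated correlation (smallest adjusted p = 0.247), and fry called 12. The 12 included the interferon response (fry adjusted p = 0.0175), NF-kappaB targets (0.0154) and fibroblast markers (0.034), which camera did not call. Camera calls that did not pass fry included G2 and mitosis (fry adjusted p = 0.194), S-phase and DNA replication (0.296), ATF4 and amino acid stress (0.503), the unfolded protein response (0.503) and hypoxia (0.535). Without probe sets that may bind several transcripts camera called 17. The calls lost were those of heat shock proteins (median 0.26, adjusted p = 0.218), mineralocorticoid and glucocorticoid receptor targets (-0.62, 0.0966), ribosome biogenesis (0.31, 0.0881) and fatty acid synthesis (0.19, 0.674). Among the calls kept, medians were then -0.60 for HLA class I presentation, 0.23 for DNA damage sensing and -0.56 for the cornified envelope.

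**Figure D3:**
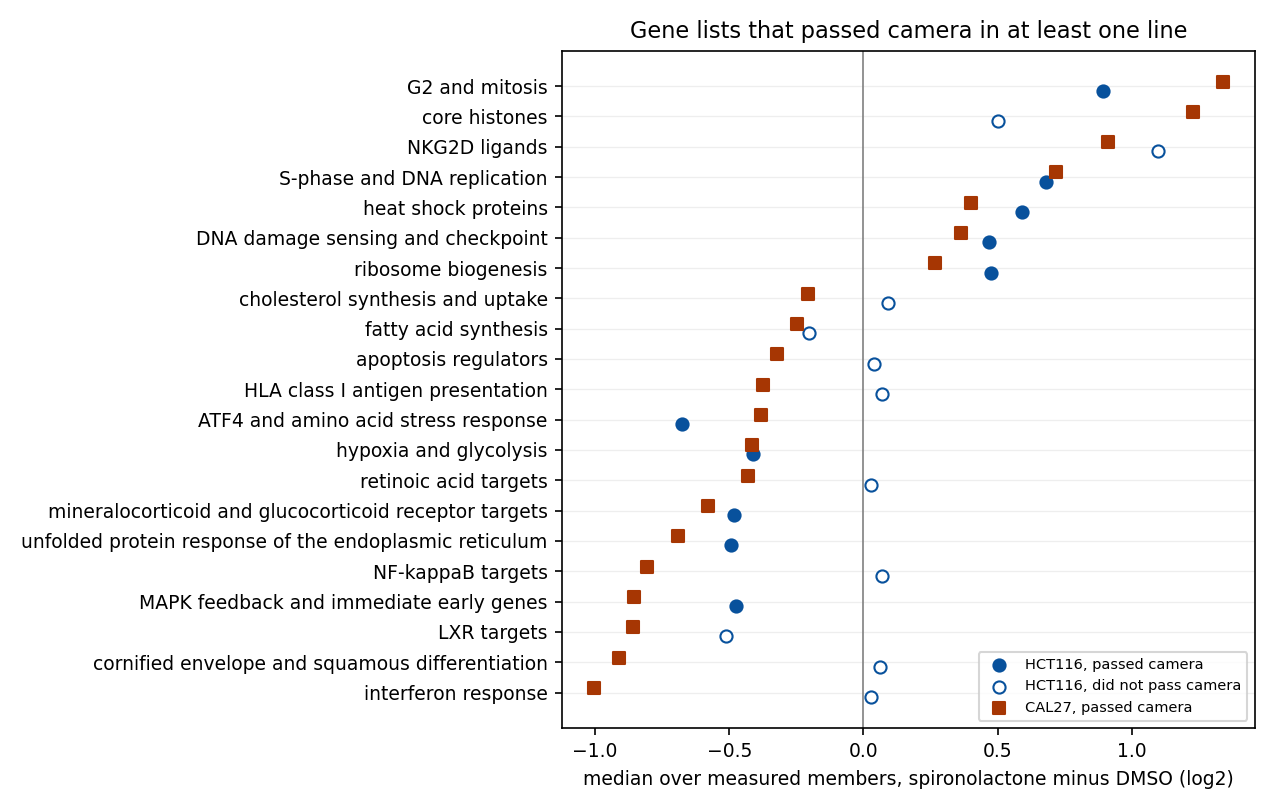
Median log2 difference between spironolactone and vehicle for the gene lists that passed camera in at least 1 line, in HCT116 and in CAL27, with filled symbols where the list passed. Medians in CAL27 ran from -1.0 for the interferon response to 1.34 for G2 and mitosis.

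The responses of the lines, which share no arrays, ran largely in the same direction. Across 13637 genes, which are not independent replicates, the log2 differences correlated at r = 0.447 (Spearman's rho = 0.483), and 66.7% had the same sign. Within the runs r was 0.457 and 0.328, and between HCT116 of one run and CAL27 of the other it was 0.333 and 0.371. Of the genes called in both lines, 183 rose in both where independent lists would give 34.8, 130 fell in both against 22.4, and 8 went opposite ways against 55.9. When each line was fitted alone, 60 rose in both against 6.27, 44 fell in both against 5.34 and 3 went opposite ways against 11.6. RAB26 fell in both lines (by 2.68 and 3.24), as did SCNN1A (by 2.33 and 2.98), DHRS3 (by 2.17 and 3.62), DDIT4 (by 2.16 and 2.58) and C1RL (by 2.64 and 2.01), while NAV3 (4.06 and 2.23) and TROAP (2.33 and 2.26) rose in both. In HCT116 other probe sets of SCNN1A and TROAP stood near 0 and that of C1RL fell less. For these genes the shared change holds for the brightest probe set alone. All 10 lists that camera called in HCT116 were called in CAL27 in the same direction, but 0 passed in either line with an estimated correlation (smallest adjusted p = 0.423 and 0.247). Of the 10, 3 were called in HCT116 without probe sets that may bind several transcripts.

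Over the arrays of both lines, spironolactone changed 3102 genes on average, 1774 higher and 1328 lower. NAV3 rose by 3.15 (adjusted p = 0.00137) and RBM24 by 2.99 (adjusted p = 0.00201), and RAB26 fell by 2.96 (adjusted p = 0.00187), DHRS3 by 2.89 (adjusted p = 0.00277) and SCNN1A, at its brightest probe set, by 2.65 (adjusted p = 0.00236). Of 32 G2 and mitosis genes 25 rose and 7 did not pass, with a median of 1.15 (camera adjusted p = 3e-10, and adjusted p = 0.657 with an estimated correlation). Of 30 S-phase and DNA replication genes 13 rose and 17 did not pass, with a median of 0.69 (camera adjusted p = 1.06e-06, and adjusted p = 0.657 with an estimated correlation). Of 31 ATF4 and amino acid stress genes 12 fell and 19 did not pass, with a median of -0.77 (camera adjusted p = 1.06e-06, and adjusted p = 0.657 with an estimated correlation). Camera called 20 lists for the average, 7 higher and 13 lower, and 0 with an estimated correlation. The share of higher genes was 57.2%, and 46.6% after cyclic loess, so the direction of the majority is not settled. The count was 957 and 1900 without treated array 1 and 2 of HCT116, and 960 and 1632 without treated array 1 and 2 of CAL27.

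**Figure D4:**
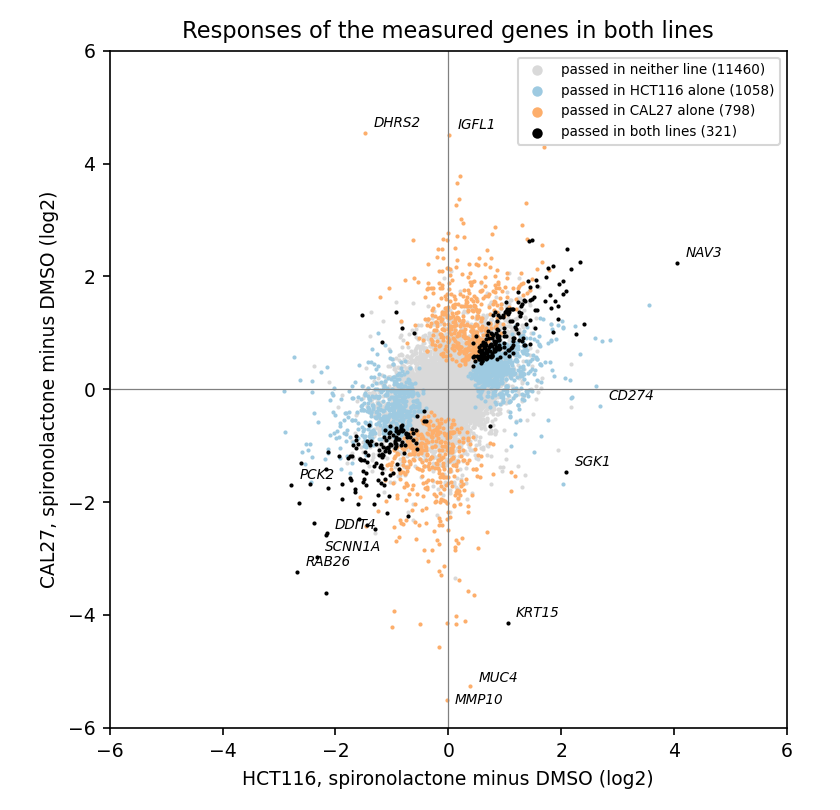
Log2 difference between spironolactone and vehicle in HCT116 (horizontal axis) and in CAL27 (vertical axis) for 13637 genes, coloured by whether a gene passed in neither line, in 1 line or in both. The 321 genes that passed in both lines lay mostly in the quadrants of equal sign, with 183 higher and 130 lower in both.

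The response itself differed between the lines for 34 genes, 19 higher and 15 lower in CAL27 than in HCT116. The largest fitted positive differences were those of DHRS2 (6.02, SE 0.85, adjusted p = 0.0378), IGFL1 (4.49, adjusted p = 0.00353), ALPP (3.50, adjusted p = 0.0181), SYNM (3.31, adjusted p = 0.00836) and IL1R2 (3.18, adjusted p = 0.00836). In HCT116 IGFL1, ALPP and IL1R2 lay below the table's median in both groups, and DHRS2 (3.19) and SYNM (3.08) after treatment, so the sizes and the order of these 5 are not fixed. The largest negative differences were those of MUC4 (-5.64, adjusted p = 0.0283), KRT15 (-5.20, adjusted p = 0.00305), SGK1 (-3.56, adjusted p = 0.0219), PTPRZ1 (-3.16, adjusted p = 0.0195) and TCIM (-3.06, adjusted p = 0.0202). Vehicle HCT116 lay below the table's median for PTPRZ1 (2.40) and TCIM (2.24), so no fall can be seen there and their differences rest on CAL27 alone. From their vehicle HCT116 levels, the falls that MUC4 and KRT15 had in CAL27 would also have ended below the table's median. The sizes and the order of the negative differences are thus not fixed. SGK1 rose by 2.09 in HCT116 and fell by 1.46 in CAL27, and KRT15 rose by 1.05 in HCT116 (adjusted p = 0.0354) and fell by 4.15 in CAL27. The difference did not pass for CD274 (-2.99, adjusted p = 0.0915), NAV3 (-1.83, adjusted p = 0.183) or THBS1 (-2.06, adjusted p = 0.356).

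Among the 4 lists that passed camera, the interferon response differed most between the lines, with a median difference of -1.12 (camera adjusted p = 1.04e-14, and adjusted p = 0.524 with an estimated correlation). In HCT116 1 of its 35 genes rose and 1 fell. NF-kappaB targets differed by -0.82 (camera adjusted p = 1.21e-07, and adjusted p = 0.37 with an estimated correlation), the cornified envelope list by -0.57 (camera adjusted p = 0.00372, and adjusted p = 0.595 with an estimated correlation) and G2 and mitosis by 0.49 (camera adjusted p = 0.0413, and adjusted p = 0.809 with an estimated correlation). Without probe sets that may bind several transcripts the interferon difference passed (adjusted p = 1.8e-13), and those of NF-kappaB targets (median -0.31, adjusted p = 0.0562), the cornified envelope (-0.28, 0.277) and G2 and mitosis (0.37, 0.192) did not. In vehicle HCT116 the NF-kappaB target CCL20 (2.94 and 2.54) and the cornified envelope gene KRT13 (2.05 and 2.84) lay below the table's median, where no fall can be seen. Other members lay above it, such as IER3 (12.10 and 12.01) and ELF3 (9.51 and 9.07). Room to fall was not tested for either list. LXR targets differed by -0.61 (adjusted p = 0.0506), and passed with the run as a block (adjusted p = 0.0379), but not at adjusted p = 0.595 with an estimated correlation. They stood at -0.22 without probe sets that may bind several transcripts (adjusted p = 0.391). For the other lists called in CAL27 alone the difference between lines did not pass. The limma count of 34 genes, beside 1740 at an unadjusted p under 0.05, was 147 with the run as a block, 109 without vehicle array 2 of HCT116, 0 without treated array 1 or 2 of HCT116, 88 without vehicle array 1 of CAL27, and 2 without treated array 1 or 2 of CAL27.

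Vehicle-treated CAL27 and HCT116 differed in 6003 genes, 2757 higher and 3246 lower in CAL27, and after cyclic loess 3012 were higher and 2913 lower, so the direction of the majority is not settled. Squamous epithelium markers were higher in CAL27 for 11 of 12 measured genes, as when adjusted over the list alone, with the basal keratins KRT14 at 8.34 (adjusted p = 7.49e-07) and KRT5 at 7.71 (adjusted p = 1.16e-07), TRIM29 at 6.94 and the desmosomal cadherin DSG3 at 6.59. All 4 lay below the table's median in vehicle HCT116, at 2.60, 2.71, 3.15 and 2.19, so these differences are lower bounds without an order. Their median difference was 4.76 (camera adjusted p = 2.36e-09, and adjusted p = 0.188 with an estimated correlation). Of 7 intestinal epithelium markers 2 were lower in CAL27 and 5 did not pass, as over the list alone. KRT8 differed by -1.87 (adjusted p = 0.000593), KRT18 by -1.10 (adjusted p = 0.0072), KRT20 by -1.02 (adjusted p = 0.0903) and CDX2 by -0.55 (adjusted p = 0.1), and the list's median of -0.55 did not pass (camera adjusted p = 0.202). Interferon response genes were higher in vehicle CAL27 for 35 of 35 members, by a median of 4.97 (camera adjusted p = 2.17e-26, and adjusted p = 0.188 with an estimated correlation), with lower bounds for members such as MX2 and RSAD2 (2.35 and 2.44 in vehicle HCT116). Over all genes the median difference was -0.10, and -0.04 after cyclic loess.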

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

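The tests on interferon response genes below the 75th percentile were chosen after the result was seen. The results of this part were singled out because the response to spironolactone differed between CAL27 and HCT116 by a test of the difference itself, which 34 genes passed. On the log2 scale and as CAL27 minus HCT116, these differences included DHRS2 at 6.02, IGFL1 at 4.49, ALPP at 3.50, SYNM at 3.31 and IL1R2 at 3.18. In the other direction they included MUC4 at -5.64, KRT15 at -5.20, SGK1 at -3.56, PTPRZ1 at -3.16 and TCIM at -3.06. Vehicle means of IGFL1 were 2.60 in HCT116 and 3.51 in CAL27, while those of ALPP (2.63) and IL1R2 (2.92) in HCT116 also lay below the table's median, so the sizes and order of these differences are not fixed. PTPRZ1 and TCIM lay below it in vehicle HCT116 as well, at 2.40 and 2.24, so no fall can be seen there and their differences are open to the same lack of room to fall as those of dim interferon genes. MUC4 stood at 5.01 in vehicle HCT116 and at 9.28 in vehicle CAL27. Its fall in CAL27 could not be seen in full from the HCT116 level, as it would end below the table's lowest value. KRT15 stood at 5.88 in vehicle HCT116, from which its fall in CAL27 would end below the table's median. The sizes of these negative differences are therefore not fixed either. DHRS2 stood at -1.48 in HCT116 (adjusted p = 0.148) and rose by 4.54 in CAL27.

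As lists, the median difference between the responses was -1.12 for the interferon response (adjusted p = 0.524 with an estimated correlation), -0.82 for NF-kappaB targets (adjusted p = 0.37 with an estimated correlation), -0.57 for the cornified envelope and squamous differentiation (adjusted p = 0.595 with an estimated correlation), and 0.49 for G2 and mitosis (adjusted p = 0.809 with an estimated correlation). Without probe sets that may bind several transcripts the interferon response passed and the others did not, with medians of -0.31, -0.28 and 0.37 (adjusted p = 0.0562, 0.277 and 0.192). Room to fall in HCT116 was not tested for NF-kappaB targets or the cornified envelope. Both hold members below the table's median in vehicle HCT116, such as CCL20 and KRT13.

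The interferon response list shifted downward in CAL27 (median -1.0) and stood at 0.03 in HCT116, where its genes were far dimmer under vehicle. Low levels that leave no room to fall in HCT116 were tested on the 9 members above the table's 75th percentile in vehicle arrays of both lines: their median difference was -0.68, and 9 of 9 responded lower in CAL27 (two-sided exact sign-flip permutation p = 0.00391, over genes, which are not independent replicates), which argues against this explanation for these members. Of the other 26 members, 10 lay at 3.79 to 5.67 in vehicle HCT116, and the fall they had in CAL27 would have left them above the table's median there. Their median difference was -1.04, with 10 of 10 lower (exact sign-flip permutation p = 0.00195, over genes). They were picked after the result by their own fall in CAL27, which is part of the tested difference, so no conclusion is drawn from them. For the remaining 16, at a median of 3.24, the difference of -1.12 cannot be told apart from a lack of room to fall. A single deviating CAL27 array was argued against as well, because the median in CAL27 stayed between -0.81 and -1.07 when each of its 4 arrays was left out. A biological difference between the lines stays open and untested, on a list with adjusted p = 0.268 with an estimated correlation in CAL27, and giving HCT116 interferon before the drug would test whether a fall needs induced levels.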

How the results depend on the processing

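Camera with both an estimated correlation and the run as a replicate block was chosen after the data were seen. Of 212 named results that passed, 197 lost the call in at least 1 of the fits without 1 array and 201 in at least 1 other setting. Without 1 array 1039 of 1678 values stayed on their side of the threshold, 639 no longer passed and 0 changed sign, with the lone array of a group assumed to vary like the others. In the other settings 1569 of 2030 stayed, 448 no longer passed and 13 changed sign. The replicate block by run ended 0 of the 212 calls and raised the counts of changed genes to 2255 in HCT116, 1904 in CAL27 and 147 for the difference between lines. Of the lists it added NKG2D ligands, cell-cycle inhibitors and core histones in HCT116 and LXR targets for the difference between lines, and it changed no other list call in these contrasts. Without moderation 198 of the 212 calls ended, and the counts were 29 in HCT116, 49 in CAL27, 862 for the average and 2 for the difference. Without the variance trend they were 815 in HCT116, 731 in CAL27 and 20 for the difference. The mean of all probe sets gave 770 genes in HCT116, and the 4 HCT116 arrays alone gave 428. A 2-fold threshold left 617 genes in HCT116, 689 in CAL27, 637 for the average and 3671 between vehicle-treated lines, by construction. Lists called numbered 3 in HCT116 without probe sets that may bind several transcripts, 0 and 0 in HCT116 and CAL27 with an estimated correlation, also 0 and 0 with the block added (smallest adjusted p = 0.662 and 0.294), and 1 and 12 with fry. The correlation of the lines' responses was 0.499 over genes above the 75th percentile. Except where construction is named, the cause was not tested.

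Without 1 array the counts ran from 0 to 1836 in HCT116, 10 to 1643 in CAL27, 957 to 3464 for the average, 0 to 109 for the difference between lines and 4928 to 5552 between vehicle-treated lines. Called lists ran from 9 to 12 in HCT116 and 16 to 20 in CAL27, and the correlation of responses from 0.379 to 0.458. Signs turned where another probe set stood for the gene or was averaged in, by construction. With the mean of probe sets in HCT116 MCL1 stood at 0.34 and CD44 at 0.23. Without probe sets that may bind several transcripts, HCT116 values were THBS1 -0.13, RBM19 -0.021, RAD50 -0.85, HSPA4 -0.96, MCL1 1.20, RIGI -0.26 and TSR1 -0.51, and CAL27 values NEDD4L -0.18, HSPA4 -1.09 and KRT8 -0.40. RIGI stood at -0.10 when the 4 HCT116 arrays alone chose the brightest probe set. Signal over background limits the 6137 dim genes, RXRG among them, for which no change can be read.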

Other observations

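The tests of RNA degradation and of bright probe sets in each line alone were chosen after the results they bear on were seen. Counts adjusted over the list alone were the same unless given. Of 28 p53 targets, 2 rose in HCT116, TIGAR by 1.44 and FAS by 1.39 (camera adjusted p = 0.738), and in CAL27 TIGAR rose by 0.80 while TRIM22 and PMAIP1 fell by 1.23 and 0.67 (0.578). Of 10 death receptor genes FAS and TNFRSF10A, at 1.03, rose in HCT116 (3 when adjusted over the list alone; camera adjusted p = 0.559), and TNFRSF25 fell by 0.97 in CAL27 (0.711). Of 11 immune checkpoint ligands CD274 rose in HCT116 (camera adjusted p = 0.805, with a median of -0.03 and a mean of 0.25). In CAL27 NT5E, the ectonucleotidase that makes adenosine, rose by 2.33 and the tryptophan-degrading IDO1 fell by 2.86 (2 lower when adjusted over the list alone; camera adjusted p = 0.773). None of 10 other ligands of NK-cell receptors passed in HCT116 (camera adjusted p = 0.691), with NECTIN2 at 0.63 (adjusted p = 0.101; another probe set at -0.81), or in CAL27 (0.578), with CLEC2D at -0.79 (adjusted p = 0.0721). In HCT116 PSME1 fell by 0.79 among 18 genes of HLA class I presentation (0 when adjusted over the list alone; camera adjusted p = 0.805). Among 24 NF-kappaB targets TNFAIP3 rose by 1.10 and IER3 fell by 0.72 there (0.805), and among 35 interferon response genes RIGI rose by 1.09, with other probe sets at -0.26 and -0.10, and ISG20 fell by 1.20 (4 higher and 2 lower when adjusted over the list alone; 0.864).

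Of 14 genes for RXR and its heterodimer partners PPARA fell in HCT116 by 1.48, with other probe sets from -1.43 to 0.20, and NR4A2 by 1.33 (1 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.322). In CAL27 NR4A1 fell by 2.61 and RARA rose (2 lower when adjusted over the list alone; 0.578). DHRS3 fell by 2.17 among 12 retinoic acid targets in HCT116 (camera adjusted p = 0.991), and SCD by 0.71 among 11 LXR targets (3 lower when adjusted over the list alone; 0.228), with other probe sets from -0.64 to 0.81. Of 16 PPAR targets ACADVL fell by 1.19 in HCT116 (camera adjusted p = 0.305), and VNN1 and ACADVL by 2.02 and 0.96 in CAL27 (1 higher when adjusted over the list alone; 0.575). Of 9 PXR and CAR targets ABCC2 fell by 2.16 in HCT116 (1 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.791; median 0.16, mean -0.34), and none passed in CAL27 (0.797). None of 8 aryl hydrocarbon receptor targets passed in HCT116 (camera adjusted p = 0.96), while AHRR rose by 1.71 and ALDH3A1 fell by 1.11 in CAL27 (0.711). Only 2 steroid receptor genes were measured, too few to test as a list, and neither ESR1 nor NR3C1 passed in either line, although NR3C1 passed in CAL27 (0.49) when adjusted over the list alone. In HCT116 LSS, SREBF2 and GGPS1 fell by 1.14, 0.83 and 0.49 among 21 cholesterol genes (4 lower when adjusted over the list alone; camera adjusted p = 0.864), and FADS1 and ACSS2 by 1.15 and 0.77, with SCD, among 13 genes of fatty acid synthesis (1 higher and 4 lower when adjusted over the list alone; 0.144).

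Cell-cycle inhibitors passed in HCT116 with the run as a block (adjusted p = 0.0463) and not without it (camera adjusted p = 0.0666, and adjusted p = 0.772 with an estimated correlation): of 10 members RBL2 fell by 1.63 and CDKN2B by 1.60 (4 lower when adjusted over the list alone). In CAL27 RBL2 fell by 0.90 and BTG1 by 0.55 (3 lower when adjusted over the list alone; camera adjusted p = 0.07). Core histones in HCT116 also passed with the block (adjusted p = 0.0452) and not without it (camera adjusted p = 0.0666, and adjusted p = 0.882 with an estimated correlation), with H2BC12 up by 1.45, H2BC21 by 1.12 and H2BC5 by 0.67 among 9 (4 higher when adjusted over the list alone). Of 20 genes of TFIIH and nucleotide excision repair GTF2H5 rose by 0.86 beside ERCC3 in HCT116 (3 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.805) and none passed in CAL27 (0.93). Of 19 apoptosis regulators BID rose by 0.75 and MCL1 fell by 0.58 in HCT116, with other probe sets of MCL1 from 0.04 to 1.20 (camera adjusted p = 0.791). Of 14 TGF-beta targets CCN2 rose by 2.03 and BHLHE40 fell by 1.19 in HCT116 (camera adjusted p = 0.791), and ID1 and BHLHE40 fell by 2.36 and 1.65 in CAL27 (1 higher and 3 lower when adjusted over the list alone; 0.578). Of 11 WNT targets CD44 fell in HCT116 (camera adjusted p = 0.918), and in CAL27 DKK1 rose by 1.09 and MYC fell by 0.76 (2 higher when adjusted over the list alone; 0.711). Of 20 NRF2 targets ABCC2 fell in HCT116 (camera adjusted p = 0.666), and in CAL27 PIR and PGD fell by 1.99 and 0.79 and AKR1B10 rose by 1.87 (3 lower when adjusted over the list alone; 0.578). None of 7 metallothioneins passed in HCT116 (1 lower when adjusted over the list alone; camera adjusted p = 0.108), with MT2A at -0.62 (adjusted p = 0.0539), or in CAL27 (1 higher when adjusted over the list alone; 0.711), with MT1M at 1.06 (adjusted p = 0.059).

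Of 30 genes of oxidative phosphorylation NDUFA9 rose by 0.78 in HCT116 (camera adjusted p = 0.528), and none passed in CAL27 (0.217). Of 23 genes of lysosome and autophagy GABARAPL1 fell by 0.71 in HCT116 (0 when adjusted over the list alone; camera adjusted p = 0.791) and NEU1 rose by 0.97 in CAL27 (2 higher and 1 lower when adjusted over the list alone; 0.464). Squamous markers SERPINB5 and TRIM29 rose by 1.53 and 0.97 in HCT116 among 12 (camera adjusted p = 0.364), while their other probe sets stood at -0.06 and from -0.50 to -0.16, and KRT13 fell in CAL27 (0.663). Of 20 cornified envelope genes ELF3 fell by 1.45 in HCT116 (0.979). None of 7 intestinal markers passed in HCT116 (0.781), and KRT8 rose by 1.41 in CAL27 (2 higher when adjusted over the list alone; 0.711), with another probe set at -0.40. Of markers of other cell types 0 of 5 fibroblast, 0 of 8 leukocyte and 0 of 3 erythroid and endothelial genes passed in HCT116 (camera adjusted p = 0.791, 0.979 and 0.805). In CAL27 the collagen gene COL1A2 rose by 1.12 (0.578), the integrin gene ITGB2 rose by 1.10 (2 lower when adjusted over the list alone; 0.746) and none of the 3 passed (0.793).

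Between the vehicle-treated lines, 16 of 18 genes of HLA class I presentation were higher in CAL27, with a median of 2.39 (camera adjusted p = 9.29e-12, and adjusted p = 0.299 with an estimated correlation), and 18 of 24 NF-kappaB targets were higher and 1 lower, with a median of 4.06 (9.29e-12, and adjusted p = 0.171 with an estimated correlation). All 9 core histones were higher in CAL27, by a median of 3.03 (camera adjusted p = 1.18e-06, and adjusted p = 0.299 with an estimated correlation). Ribosome biogenesis was lower in CAL27 for 20 of 25 genes, with a median of -1.07 (camera adjusted p = 1.72e-05, and adjusted p = 0.537 with an estimated correlation). Differences of members below the table's median in 1 line are lower bounds.

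On the number of genes changed on average, the 8 arrays allow 18 splits within lines, of which the real one, 1 split, called 3102 genes and the highest of the others 34. With 18 splits no share under 0.05 can be had. Among the 8 splits that part all 4 pairs of same-run arrays of a line, the highest other count was 34, and among the 10 that part fewer pairs it was 8.

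By camera the list of G2 and mitosis shifted upward and that of ATF4 and amino acid stress downward in both lines (adjusted p = 0.922 and 0.882 in HCT116 and adjusted p = 0.553 and 0.768 in CAL27 with an estimated correlation), although 0 of 32 G2 and mitosis genes passed in HCT116 and the ATF4 median was 0.24 in run 2 of CAL27. Scaling differences left between the deposited arrays were argued against as the cause, since cyclic loess or median centring moved none of the 4 list medians by more than 0.095 and all 4 calls held. The deposited arrays were already aligned, with medians of 3.20 to 3.24. What the normalization before deposit itself introduced could therefore not be tested. Denser vehicle wells at collection remain open: 18 measured targets of YAP and TAZ, which are high in sparse cells, a list drawn up after these shifts were seen, without CCN2 and ANKRD1 but with NT5E, which rose in CAL27, had a median of 0.03 in HCT116 (camera p = 0.993) and of 0.44 in CAL27 (camera p = 0.00208, and 0.144 with an estimated correlation). They passed in CAL27 alone, while CCN2 stood at 2.03 in HCT116 and -1.67 in CAL27 and ANKRD1 at 0.22 and 3.02, so these genes do not decide the question. The growth state of the cells at collection may therefore differ between drug and vehicle, and the sample labels state no time for the vehicle arrays. Cell counts at collection would be needed to separate growth state from an action of the drug on these genes.

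Probe sets of the same gene were called in opposite directions for 53 of 431 genes with at least 2 called probe sets in HCT116 (12.3%), 12 genes in CAL27 (3.42%) and 193 of 1140 for the average (16.9%), among them MSI2 (2.54 and -1.56), PURB (1.27 and -2.76) and CNPY3 (1.93 and -2.15) in HCT116, chosen after their values were seen. Array noise was argued against, since 98.1% of the 53 genes had their probe sets in the same order in CAL27 (exact binomial p = 1.2e-14). Among bright probe sets without shared-probe suffixes the share was 20.7% in HCT116 and 24.8% for the average, so it did not fall from that over all probe sets. It exceeded the 5.94% between the vehicle-treated lines (Fisher's exact p = 2.07e-05 and 1.41e-12). Differences between the lines were larger, which by itself favours probe sets of equal direction, so this comparison cannot decide on dim or cross-hybridising probe sets. They stay open, also for CAL27, at 8.57% (Fisher's exact p = 0.427), and at 3.42% over all probe sets against 6.45% (Fisher's exact p = 0.0229). RNA degradation differing with treatment stays open: the difference between 3′ and 5′ probe sets of ACTB and GAPDH moved upward, as degradation predicts, in both runs of HCT116, by 0.03 to 0.20, while in CAL27 that of ACTB moved by -0.20 and 0.09 and that of GAPDH by 0.10 and -0.03, and although the gaps between opposed probe sets in HCT116 were wider, at 1.45 to 4.10, those genes were chosen for opposite calls and 2 control transcripts set no bound for them. A change in transcript ends or isoforms with spironolactone is another candidate explanation and a hypothesis only, which mapping the probes to transcript ends would test.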
